A study of Homo sapiens with 6 samples.

How the data were processed

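The series holds 6 single-channel Affymetrix arrays of the human cell line THP-1, with total RNA labelled with biotin by the Affymetrix protocol. They are 3 of unstimulated cells and 3 of cells differentiated with PMA. Per the labels' protocols, cells were grown in RPMI medium with 10% FBS, 2.5 mM glutamate and 0.05 mM mercaptoethanol, differentiated with 200 nM PMA for 3 days and rested without it for 3 days, and RNA was extracted with Trizol. The authors' deposited table holds log2 values, 1 per probe set and array, with quartiles and medians that differ slightly between arrays. Per the submitters' processing notes, RMA and Partek were used; their versions are not given in the sources used here. RMA corrects background, quantile-normalizes and summarises probes, which draws the arrays towards a common distribution and compresses changes near background.

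Probe sets were named through the platform annotation, whose gene IDs were matched to the current gene table (GRCh38.p14) for 19429 of the 19460 probe sets with a single symbol. Of 33297 probe sets, 1754 carried several symbols and 12083 were not named there; neither kind was tested in the main comparison. Where several probe sets named a gene (769 genes), the one with the highest mean over all 6 arrays stood for it, giving 18417 genes. No gene had probe sets past the threshold in opposite directions, among 155 genes with at least 2 such probe sets. No filter on dim probe sets was applied.

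Samples were grouped by the titles and descriptions in the labels. Log2 values were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, group as the only term, 7.71 total degrees of freedom), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05; a second count also asked for a 2-fold change. The median standard error of a log2 fold change was 0.115. For 47 gene lists fixed before the data were examined (1103 entries, 1000 of them measured alone), limma's camera was run two-sided with a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and members were also counted adjusted over the list alone. The design, the alternatives and the rule for named genes were set before the data were examined. The rule took the 12 largest and 12 smallest log2 fold changes among genes past the threshold whose groups did not overlap, up to 4 members past the threshold per list (3 in the direction most took, 1 in the other), and 17 genes whatever their values. The report names part of the genes the rule allows, and this choice was made after the results were seen. It left out all 23 rule genes past the threshold whose call was lost without some array, along with others that kept theirs. The examples in the report are therefore steadier to the loss of an array than the rule's genes as a whole, and the 23 are named in the closing section. They are not steady under every alternative. By the gene-wise test without shared variance, 53 of the rule's genes lost their call. Examples in the report were among them, such as CD14 (adjusted p = 0.105), LSS (0.092) and ITGAX (0.0859). Genes outside the rule are named only in the closing section, where this is said.

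The steps were tested on simulated data with the real genes' means and spreads (20 runs, 18417 genes, 200 changed genes per run). Of simulated genes changed 1.5-fold, 41.1% were called, of those changed 2-fold 78.3%, and of those changed 4-fold 96.8%, all in the right direction, with 4.2% false among the calls. Besides the 200 genes, only the members of the shifted lists were changed, far fewer than the 26.4% of genes called in the real data. The adjusted threshold depends on that share, so these percentages need not hold for the real comparison. Camera called 100% of lists shifted by 0.5 on the log2 scale and 0.8% of the others; the simulated genes were independent of each other, which real genes are not.

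Alternatives to the main choices were run as follows. They covered the normalization (quantile normalization repeated, centring on medians, cyclic loess), dim genes (lowest 25% or those below the median left out), the probe set standing for a gene, every probe set of the table, the variance model (trend and robust, array quality weights, a gene-wise test without shared variance), a replicate block, an adjusted p of 0.01, treat against a 1.5-fold change, and a 4-fold threshold. Each array was left out in turn. For the lists, an estimated correlation, ranks and fry were also run. An alternative that left out both arrays standing apart from their groups was chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.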

Results

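Gene expression was measured in THP-1 cells, a line grown from a monocytic leukaemia, before and after differentiation with PMA, a phorbol ester that activates protein kinase C. The labels describe 3 arrays of unstimulated cells and 3 arrays of cells that received 200 nM PMA for 3 days and then rested without it for 3 days. Each array gave 1 log2 value per probe set, with array medians between 6.10 and 6.25. A single gene symbol was carried by 19460 probe sets, and 18417 genes were tested. Pearson correlations over all probe sets were 0.988 to 0.995 within a group and 0.958 to 0.968 between groups. The first principal component (72.4% of the variance) separated the groups. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical, and the number of arrays limits the precision.

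The comparison asked which genes differed between macrophage-like THP-1 cells made with PMA and the unstimulated line. Collagenases, fibronectin, inflammatory mediators and a scavenger receptor were among the largest rises, and primary granule genes were among the largest falls. MMP8, a neutrophil collagenase, went from 3.21 ± 0.07 in unstimulated cells to 11.76 ± 0.46 with PMA (mean log2 value ± SD, n = 3 each). CTSG, the granule protease cathepsin G, went from 12.25 ± 0.12 to 5.60 ± 0.19 (n = 3 each), a 101-fold fall. In limma with Benjamini-Hochberg adjustment, 4854 genes (26.4% of those tested) passed an adjusted p of 0.05, 2431 higher and 2423 lower in PMA-differentiated cells. Of these, 1542 changed at least 2-fold, 952 higher and 590 lower, and 469 changed at least 4-fold, 325 higher and 144 lower. The groups did not overlap for 7595 genes (41.2%), where chance gives 10%. The balance of rises and falls depended on scaling and on the probe sets tested. With each array centred on its median, 61.8% of the called genes were higher, against 50.1% here. When every probe set was tested, 40.8% of those called were higher. Among changes of at least 2-fold, these shares were 68.5%, 61.7% and 52.4%, in the same order.

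In the following, a value after a gene is its log2 fold change, PMA-differentiated minus unstimulated, ± its standard error in the limma fit with n = 3 arrays per group. The 12 largest rises were MMP8 (8.56 ± 0.21), the interstitial collagenase MMP1 (7.01 ± 0.18), fibronectin FN1 (6.61 ± 0.29), the cytokine IL1B (6.58 ± 0.31), the chemokine CCL20 (6.55 ± 0.64), the protease inhibitor TFPI2 (6.26 ± 0.65), the tryptophan-degrading enzyme TDO2 (6.09 ± 0.28), the scavenger receptor MSR1 (5.99 ± 0.28), the cell fusion protein DCSTAMP (5.85 ± 0.59), the proton pump subunit ATP6V0D2 (5.76 ± 0.20), RGS1 (5.74 ± 0.43) and EMP1 (5.54 ± 0.17). Their adjusted p-values lay between 7.29e-07 and 0.000381. The 12 largest falls were MS4A3 (−6.90 ± 0.17), CTSG (−6.65 ± 0.12), the retinol dehydrogenase family member DHRS9 (−5.97 ± 0.12), PLAC8 (−5.72 ± 0.24), TARP (−5.71 ± 0.32), GPR160 (−5.59 ± 0.17), MS4A6A (−5.55 ± 0.16), the chemokine receptor CCR2 (−5.48 ± 0.22), PPP1R27 (−5.21 ± 0.20), SERPINB10 (−4.98 ± 0.17), and the granule proteins AZU1 (−4.86 ± 0.13) and neutrophil elastase ELANE (−4.85 ± 0.12), with adjusted p-values between 5.48e-07 and 2.15e-05. CCL20, TFPI2 and DCSTAMP were lower on the PMA replicate 3 array (9.55, 8.52 and 8.56) than on the other PMA arrays (CCL20 11.86 and 12.34, TFPI2 10.77 and 11.45, DCSTAMP 10.99 and 10.96), and all 3 stayed above every unstimulated array. The lower group's mean lay below every array's lower quartile (4.46 to 4.57) for MMP8, TFPI2, DCSTAMP, ATP6V0D2, MS4A3, DHRS9, CCR2 and SERPINB10, where signal cannot be told from background, so the size and order of these changes are uncertain. TARP depended on the probe set: 2 of its 3 probe sets held −5.71, the other did not pass (0.14, adjusted p = 0.503), and their mean gave −3.76.

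**Figure D1:**
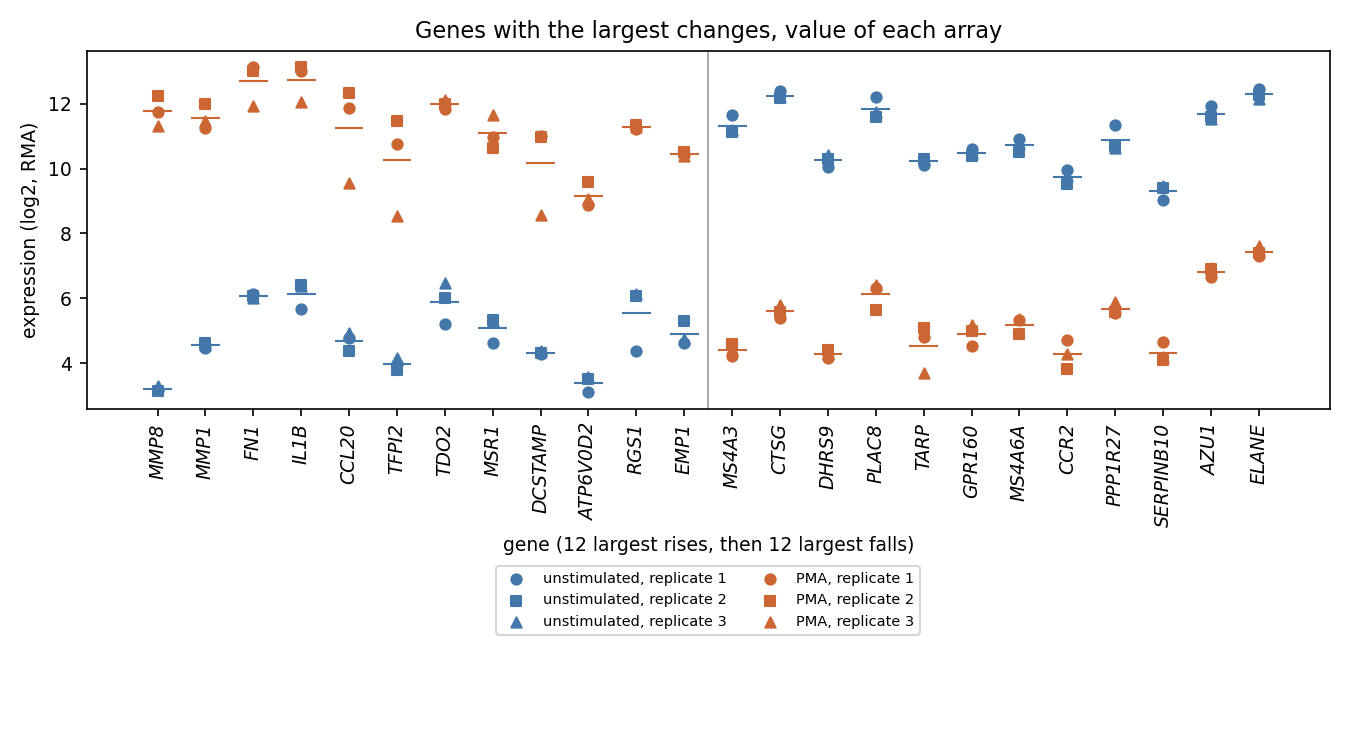
Log2 expression (RMA, y axis) of the 12 genes with the largest rises and the 12 with the largest falls (x axis) on each of the 6 arrays; colours mark the groups, symbols the replicates and short lines the group means (n = 3). MMP8 lies at 3.21 in unstimulated and 11.76 in PMA-differentiated cells on average, CTSG at 12.25 and 5.60, and the PMA replicate 3 array is lowest of the PMA arrays for CCL20, TFPI2 and DCSTAMP.

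Of the 47 gene lists fixed before the data were examined, 21 passed an adjusted p of 0.05 in limma's camera test with a preset inter-gene correlation, 14 up and 7 down. None of the 47 passed with an estimated correlation, so that p is given beside each call. By fry, which tests whether a list's own genes move on balance one way, 24 lists passed: 16 of the 21 and 8 others, each noted below. Macrophage surface markers rose as a list (adjusted p = 0.000104; adjusted p = 0.429 with an estimated correlation): of 22 measured, 12 rose and 1 fell, and 13 and 1 did so adjusted over the list alone. MSR1 led, followed by the haemoglobin scavenger receptor CD163 (3.44 ± 0.20) and the lipopolysaccharide co-receptor CD14 (2.46 ± 0.53). The complement receptor chains ITGAM (2.01 ± 0.12) and ITGAX (1.70 ± 0.33), the lipid scavenger receptor CD36 (2.43 ± 0.39) and the M-CSF receptor CSF1R (1.94 ± 0.18) also rose. CD14 was 7.51 on the unstimulated replicate 1 array and 9.67 and 9.65 on the other unstimulated arrays. CD68, a lysosomal glycoprotein used as a macrophage marker, was already at 11.65 ± 0.13 in unstimulated cells and did not pass (−0.24 ± 0.10, adjusted p = 0.136). The mannose receptor MRC1 did not pass either (1.62 ± 0.69, adjusted p = 0.130); it was 7.80 on the PMA replicate 3 array and 4.97 and 5.01 on the others. Without PMA replicate 3 it passed with a log2 fold change of 0.69 (adjusted p = 0.0101).

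Genes of the lysosome and its acidification rose together. Of 26 lysosomal hydrolases and membrane proteins, 16 rose and 2 fell (17 and 2 adjusted over the list alone; list adjusted p = 3.68e-08; adjusted p = 0.332 with an estimated correlation). The cysteine proteases CTSL (2.67 ± 0.12), CTSH (2.03 ± 0.14) and LGMN (2.00 ± 0.17) changed most. Of 17 subunits of the V-ATPase, the proton pump of lysosomes, 11 rose and none fell (15 and 0 adjusted over the list alone; list adjusted p = 1.70e-08; adjusted p = 0.171 with an estimated correlation), led by ATP6V0D2, TCIRG1 (1.21 ± 0.14) and ATP6AP2 (1.06 ± 0.10). Osteoclast markers, which share ATP6V0D2 and DCSTAMP with the largest rises, rose as a list with 7 of 11 higher and 1 lower (the same counts adjusted over the list alone; list adjusted p = 0.00254; adjusted p = 0.429 with an estimated correlation). The member that fell was carbonic anhydrase CA2 (−3.88 ± 0.58). ATP6V0D2, MMP9, ITGB3, ACP5 and CTSK were also entries of the V-ATPase, matrix, integrin or lysosomal lists, so this call was not separate from theirs. Among 19 genes of lipid uptake, storage and efflux, 10 rose and 1 fell (10 and 2 adjusted over the list alone; list adjusted p = 0.000321; adjusted p = 0.276 with an estimated correlation). MSR1, the fatty acid binding protein FABP4 (4.49 ± 0.77) and the oxidised LDL receptor OLR1 (2.93 ± 0.33) rose most, and the mitochondrial thiolase ACAT1 (−0.93 ± 0.15) fell. FABP4 was 4.43 on the unstimulated replicate 1 array, against 6.60 and 6.76 on the other unstimulated arrays. On the PMA replicate 3 array it was 11.87, against 10.08 and 9.31 on the other PMA arrays. Its log2 fold change ran from 3.01 to 5.04 over the alternatives.

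Matrix and adhesion genes made up the lists with the highest medians. Of 25 matrix proteins and matrix proteases, 20 rose and 1 fell (21 and 1 adjusted over the list alone), with a median log2 fold change of 1.98 (list adjusted p = 7.54e-13; adjusted p = 0.266 with an estimated correlation). MMP8, MMP1 and FN1 led, the gelatinase MMP9 rose by 5.09 ± 0.34, and the proteoglycan VCAN (−2.89 ± 0.40) was the member that fell. Of 25 integrins and adhesion genes, 19 rose and 2 fell (20 and 2 adjusted over the list alone), with a median of 1.48 (list adjusted p = 1.43e-09; adjusted p = 0.276 with an estimated correlation). Integrin chains ITGA3 (4.71 ± 0.23) and ITGB3 (3.60 ± 0.58) and the leukocyte ligand ICAM1 (4.22 ± 0.29) rose most, and the selectin ligand SELPLG (−2.20 ± 0.13) fell. ITGB3 was 7.11 on the PMA replicate 3 array, against 8.90 and 9.76 on the other PMA arrays.

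**Figure D2:**
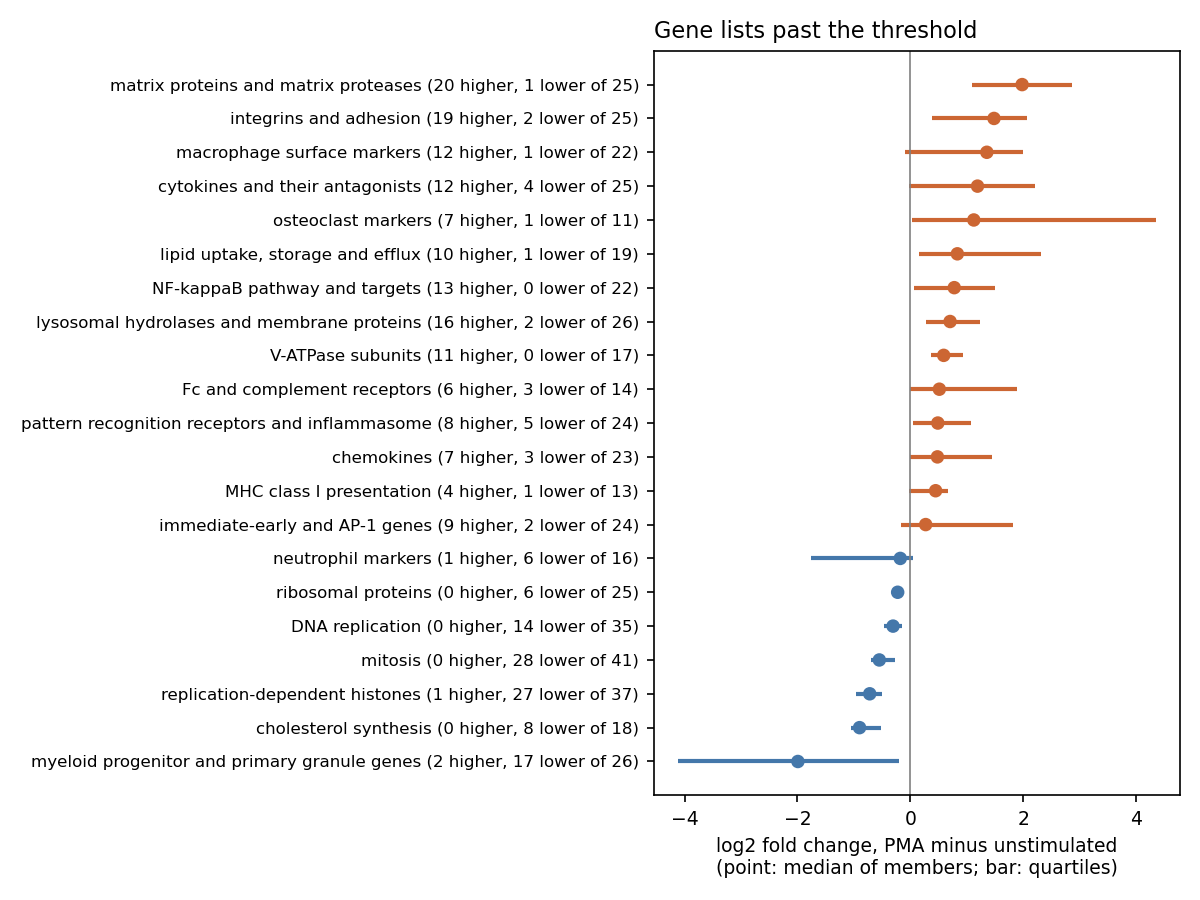
Median log2 fold change, PMA-differentiated minus unstimulated (x axis), of the members of each of the 21 gene lists past the threshold in camera with a preset correlation (y axis), with bars from the lower to the upper quartile of the members; the numbers give members that passed higher and lower out of those measured. Medians run from −1.99 for myeloid progenitor and primary granule genes to 1.98 for matrix proteins and matrix proteases.

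Inflammatory mediators moved unevenly. Of 25 cytokines and their antagonists, 12 rose and 4 fell (13 and 4 adjusted over the list alone; list adjusted p = 0.00375; adjusted p = 0.546 with an estimated correlation). IL1B, the growth factor PDGFA (4.46 ± 0.31) and the macrophage growth factor CSF1 (3.89 ± 0.56) rose, and the death ligand TNFSF10 (−2.39 ± 0.22) fell. TNF overlapped between the groups (0.62 ± 0.88, adjusted p = 0.683). It was 6.30 on the unstimulated replicate 1 array and 9.58 and 9.43 on the other unstimulated arrays. Of 23 chemokines, 7 rose and 3 fell (9 and 3 adjusted over the list alone; list adjusted p = 0.00786; adjusted p = 0.560 with an estimated correlation). CCL20 and PPBP (2.03 ± 0.40) were higher and CCL22 (−1.06 ± 0.11) was lower. By fry the list did not pass (0.0522), and without PMA replicate 3, 13 chemokines rose. Of 22 genes of the NF-kappaB pathway and its targets, 13 rose and none fell (14 and 1 adjusted over the list alone; list adjusted p = 0.000117; adjusted p = 0.429 with an estimated correlation), among them the survival gene BCL2A1 (4.52 ± 0.44) and IER3 (3.09 ± 0.41). Of 24 immediate-early and AP-1 genes, 9 rose and 2 fell (the same adjusted over the list alone; list adjusted p = 0.0125; adjusted p = 0.683 with an estimated correlation). PHLDA1 (4.25 ± 0.25), SPRED1 (3.92 ± 0.42) and the phosphatase DUSP4 (3.46 ± 0.11) rose, and the mRNA decay factor ZFP36 (−1.53 ± 0.21) fell. This list depended on the unstimulated replicate 1 array, whose median member lay 0.60 below the other unstimulated arrays. Without it the list's adjusted p was 0.183, with 8 members higher and 5 lower.

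**Figure D3:**
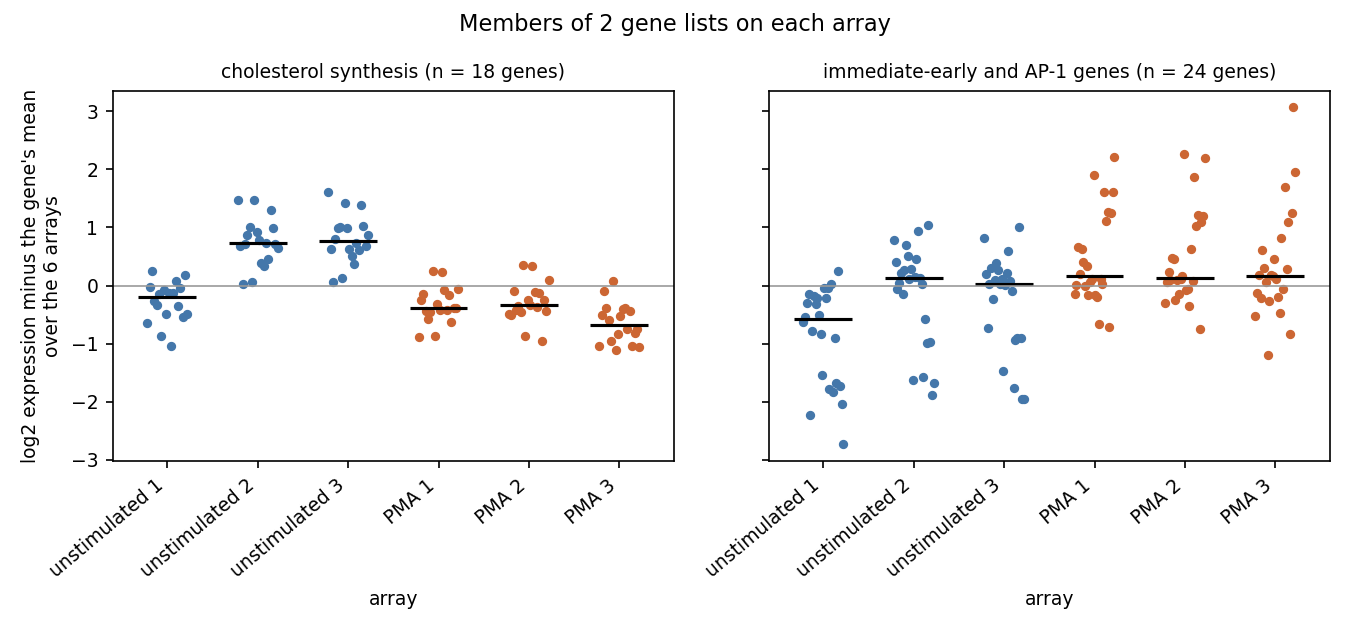
Log2 expression of each member minus that gene's mean over the 6 arrays (y axis) on each array (x axis), for 18 cholesterol synthesis genes and 24 immediate-early and AP-1 genes; each point is a gene, black lines are medians and colours mark the groups. The median cholesterol synthesis gene lies at −0.21 on the unstimulated replicate 1 array and at 0.73 and 0.76 on the other unstimulated arrays. On PMA replicates 1, 2 and 3 it lies at −0.39, −0.34 and −0.67.

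Receptors and antigen presentation were mixed. Of 24 pattern recognition receptors and inflammasome genes, 8 rose and 5 fell (13 and 5 adjusted over the list alone). The list lay at the threshold (adjusted p = 0.04997; adjusted p = 0.610 with an estimated correlation) and lost its call without PMA replicate 1 (0.0514), without unstimulated replicate 1 (0.0624) and by fry (0.287). LY96, the partner of TLR4, rose (3.37 ± 0.42), as did the DNA sensor AIM2 (3.24 ± 0.60) and TLR1 (2.59 ± 0.28), while NAIP fell (−2.74 ± 0.19) and TLR4 itself overlapped between groups (0.57 ± 0.33, adjusted p = 0.274). AIM2 lay at 3.73 to 3.99 on the unstimulated arrays, below every array's lower quartile, so the size of its rise is uncertain. It was 5.51 on the PMA replicate 3 array and 7.82 and 8.07 on the other PMA arrays. Of 14 Fc and complement receptors, 6 rose and 3 fell (7 and 3 adjusted over the list alone; list adjusted p = 0.04997; adjusted p = 0.620 with an estimated correlation), and this call was lost without PMA replicate 1 (0.0718) and without unstimulated replicate 1 (0.162). The anaphylatoxin receptor C5AR1 (3.82 ± 0.16) and the IgA receptor FCAR (2.63 ± 0.40) rose and the IgG receptor FCGR2A (−2.61 ± 0.16) fell. Both lists also lost their call under each of the 3 rescalings run (adjusted p 0.0954 to 0.136). Of 13 genes of MHC class I presentation, 4 rose and 1 fell (5 and 1 adjusted over the list alone; list adjusted p = 0.0249; adjusted p = 0.560 with an estimated correlation), with the peptidase ERAP2 (0.96 ± 0.16) and the transporter TAP1 (0.85 ± 0.14) higher and PSMB10 (−0.73 ± 0.15) lower. That call was lost without PMA replicate 1 (0.0542), without unstimulated replicate 2 (0.0603), with arrays centred on their medians (0.0508), with quantile normalization repeated (0.0523) and by fry (0.0556). MHC class II presentation did not pass as a list (adjusted p = 0.717; 2 higher and 4 lower of 13, 2 lower without unstimulated replicate 3), with HLA-DPA1 (−1.45 ± 0.17) and HLA-DPB1 (−0.97 ± 0.09) lower and the lysosomal reductase IFI30 (1.85 ± 0.15) higher. Complement components (3 higher and 3 lower of 16, 5 lower without PMA replicate 3 or unstimulated replicate 1, adjusted p = 0.463) and NADPH oxidase genes (0 of 7 past in limma, 1 at an unadjusted p of 0.05, list adjusted p = 0.918, median −0.08 and mean 0.05) did not pass. The complement regulator CD59 rose (3.12 ± 0.19) and complement factor D, CFD, fell (−2.82 ± 0.18). Interferon-stimulated genes did not pass (3 higher and 5 lower of 30, adjusted p = 0.473), with OAS3 (1.40 ± 0.28) higher and IFITM1 (−2.15 ± 0.40) and XAF1 (−1.75 ± 0.17) lower. Without unstimulated replicate 1, whose median member lay 0.53 below the other unstimulated arrays, 11 were lower and the list passed downwards (adjusted p = 0.0218).

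Cell division genes fell as groups, by modest amounts. Of 41 mitosis genes, 28 fell and none rose (29 and 0 adjusted over the list alone), with a median log2 fold change of −0.55 (list adjusted p = 5.54e-10; adjusted p = 0.528 with an estimated correlation). The kinesin KIF20A (−1.41 ± 0.14), the mitotic kinase PLK1 (−1.25 ± 0.11) and cyclin CCNB2 (−1.06 ± 0.08) fell most. Of 37 replication-dependent histone genes, 27 fell and 1 rose (31 and 1 adjusted over the list alone), with a median of −0.72 (list adjusted p = 7.19e-11; adjusted p = 0.326 with an estimated correlation). Examples are H4C3 (−1.33 ± 0.13) and H4C4 (−1.30 ± 0.11), while H2BC12 rose (1.99 ± 0.12). Histone genes are near-identical copies, so their probe sets can share signal. Of 35 DNA replication genes, 14 fell and none rose (16 and 0 adjusted over the list alone), with a median of −0.31 (list adjusted p = 3.39e-05; adjusted p = 0.620 with an estimated correlation), among them the licensing factor CDT1 (−1.05 ± 0.15) and the primase PRIM1 (−0.83 ± 0.09). By fry the replication list did not pass (0.0634). The number that fell depended on single arrays: 18 mitosis genes without PMA replicate 1, and 7, 6 and 8 replication genes without PMA replicate 1, PMA replicate 2 and unstimulated replicate 3. Nucleotide synthesis genes did not pass as a list (1 higher and 8 lower of 22, adjusted p = 0.135), with IMPDH2 lower (−0.95 ± 0.12). Without unstimulated replicate 2 the list passed (0.0205), and 5 were lower without PMA replicate 1, PMA replicate 2 or unstimulated replicate 1. The cyclin-dependent kinase inhibitor CDKN1A rose (2.43 ± 0.24), while its list of CDK inhibitors and growth arrest genes went both ways (5 higher and 6 lower of 20, adjusted p = 0.898), with GAS6 lower (−1.46 ± 0.14). The 6 lower became 2 without PMA replicate 1 or unstimulated replicate 3, and 3 without PMA replicate 2 or unstimulated replicate 2. DNA repair genes did not pass (2 higher and 5 lower of 23, adjusted p = 0.267), with CHEK2 lower (−0.88 ± 0.12) and XRCC1 higher (1.20 ± 0.14). Without PMA replicate 1 or unstimulated replicate 3, 3 repair genes were lower.

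The transcription factor gene MYC fell (−0.89 ± 0.12), and its list with ribosome biogenesis genes did not pass (1 higher and 4 lower of 31, adjusted p = 0.463) except without unstimulated replicate 2 (0.0397). Without PMA replicate 1, 1 was lower, without PMA replicate 2, 2 were, and without unstimulated replicate 1, 5 were higher. Of 25 ribosomal protein genes, 6 fell and none rose (7 and 0 adjusted over the list alone), with a median of −0.23 (list adjusted p = 0.000147; adjusted p = 0.528 with an estimated correlation). RPL10A (−0.48 ± 0.09) was among them. Fewer members passed without PMA replicate 1 (1), PMA replicate 2 (2), unstimulated replicate 2 (3) or unstimulated replicate 3 (2). The reference genes ACTB (−0.11 ± 0.09, adjusted p = 0.434) and GAPDH (−0.05 ± 0.09, adjusted p = 0.761) did not pass.

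Genes of immature and granule-forming myeloid cells fell by the largest amounts of any list. Of 26 myeloid progenitor and primary granule genes, 17 fell and 2 rose (18 and 2 adjusted over the list alone), with a median log2 fold change of −1.99 (list adjusted p = 5.99e-11; adjusted p = 0.171 with an estimated correlation). MS4A3, CTSG and SERPINB10 led, the progenitor transcription factor MYB fell by 4.27 ± 0.18 on the log2 scale, and myeloperoxidase, MPO, fell from a low level (−1.10 ± 0.18; 6.03 ± 0.28 in unstimulated cells, SD, n = 3). BPI, a bactericidal granule protein, rose (2.75 ± 0.54). Of 16 neutrophil markers, 6 fell and 1 rose (the same adjusted over the list alone; list adjusted p = 0.0327; adjusted p = 0.332 with an estimated correlation), with the G-CSF receptor CSF3R (−3.40 ± 0.25), the calcium-binding protein S100A8 (−3.36 ± 0.22) and CXCR2 (−2.46 ± 0.13) lower and MMP8 higher. The call was lost without PMA replicate 1 (0.0514). Myeloid transcription factors went both ways (5 higher and 9 lower of 32, adjusted p = 0.463). IRF8 (−3.43 ± 0.15), GFI1 (−2.90 ± 0.18) and CEBPA (−1.77 ± 0.17) fell and BHLHE41 (4.09 ± 0.42) rose, and by fry the list passed downwards (0.0121). The protein kinase C family and diacylglycerol signalling genes, which include the direct targets of phorbol esters, did not pass as a list (3 higher and 7 lower of 24, adjusted p = 0.0723). RASGRP2 (−2.32 ± 0.15) and RASGRP4 (−2.01 ± 0.20) fell and RASGRP3 (2.26 ± 0.26) rose. That list passed downwards under the 3 rescalings (adjusted p 0.0393 to 0.0413) and by fry (0.00385). Without PMA replicate 1, 1 of its members was higher.

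Cholesterol synthesis genes were lower. Of 18 genes, 8 fell and none rose (10 and 0 adjusted over the list alone), with a median log2 fold change of −0.90 (list adjusted p = 0.000532; adjusted p = 0.620 with an estimated correlation; 0.104 by fry, which did not call the list). Lanosterol synthase LSS (−1.88 ± 0.38) and the last enzyme of the pathway, DHCR7 (−1.76 ± 0.35), fell most. The median member was 1.09 lower on the unstimulated replicate 1 array than on the other unstimulated arrays. Relative to each gene's mean over the 6 arrays, it lay at −0.21 there. This was nearer the PMA arrays (−0.39, −0.34 and −0.67) than the other unstimulated arrays (0.73 and 0.76), on which the difference mostly rested. Without unstimulated replicate 1, 15 of 18 fell (median −1.21, adjusted p = 9.66e-10). Without unstimulated replicate 2 or 3 only 4 did, and without PMA replicate 1, 5 did. Glycolysis and glucose uptake genes did not pass (4 higher and 6 lower of 23, adjusted p = 0.614), with ALDOC (−2.48 ± 0.45) and the fructose transporter SLC2A5 (−1.78 ± 0.17) lower and the hexokinase HK1 (1.19 ± 0.11) higher. Respiratory chain genes did not pass (0 higher and 3 lower of 29, adjusted p = 0.135) except without unstimulated replicate 2 (0.0173) and with quantile normalization repeated (0.0459); without unstimulated replicate 1, 4 were higher. In the list of metallothioneins, iron and NRF2 targets, 6 rose and 6 fell of 22 (adjusted p = 0.659). Haem oxygenase HMOX1 (3.10 ± 0.31), GCLC (2.15 ± 0.13) and NQO1 (2.11 ± 0.14) were higher and the metallothionein MT1E (−2.59 ± 0.31) was lower. The unfolded protein response list did not pass (3 higher and 5 lower of 25, adjusted p = 0.918), with EDEM1 lower (−1.54 ± 0.16); 5 were higher without unstimulated replicate 2. Eicosanoid genes did not pass (4 higher and 1 lower of 20, adjusted p = 0.0624), though cyclooxygenase PTGS1 (2.24 ± 0.13), TBXAS1 (1.21 ± 0.16) and ALOX5AP (1.19 ± 0.14) rose. The list passed without PMA replicate 1 (0.0478), PMA replicate 3 (0.0269, with 7 higher) or unstimulated replicate 2 (0.0385), and by fry (0.0116). Without unstimulated replicate 1, 3 were higher and 3 lower (0.187). Apoptosis regulators did not pass (8 higher and 3 lower of 23, adjusted p = 0.121), with BCL2L1 (1.43 ± 0.15) higher and BCL2 (−1.85 ± 0.29) lower. By fry the apoptosis list passed upwards (0.0424), and 5 were higher without PMA replicate 1.

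Neither activation signature passed in camera. Of 19 genes of classically activated macrophages, 2 rose and 4 fell (adjusted p = 0.463), with IL1B higher and CD38 (−3.81 ± 0.58) and IRF5 (−0.93 ± 0.15) lower. Without PMA replicate 1 or unstimulated replicate 3, 2 were lower. Of 22 genes of alternatively activated macrophages, 6 rose and 4 fell (adjusted p = 0.286), with FN1, the chitinase CHIT1 (4.03 ± 0.51) and the transglutaminase TGM2 (3.47 ± 0.39) higher and F13A1 (−3.45 ± 0.37) lower. By fry the alternative list passed upwards (0.0104), and 2 were lower without PMA replicate 1 or any 1 of the unstimulated arrays. None of the lists for other cell types besides neutrophils and osteoclasts passed in camera, while dendritic (0.0337), fibroblast (0.0185) and endothelial markers (0.0424) passed upwards by fry. Dendritic cell markers had 7 higher and 1 lower of 18 (adjusted p = 0.132), with CD1C (2.09 ± 0.24) higher and FLT3 (−3.67 ± 0.34) lower, and passed without unstimulated replicate 2 (0.0475). Endothelial markers had 4 higher of 14 (adjusted p = 0.0624), with ROBO4 (2.36 ± 0.11) higher, and passed without PMA replicate 1 (0.0239) or unstimulated replicate 2 (0.0173) and with quantile normalization repeated (0.0459). Fibroblast markers had 4 higher and 1 lower of 14 (adjusted p = 0.107), with FAP (4.57 ± 0.54) and PDGFRA (3.15 ± 0.36) higher. FAP lay at 4.14 to 4.38 on the unstimulated arrays, below every array's lower quartile, so the size of its rise is uncertain. T and NK cell markers had 2 higher and 1 lower of 19 (adjusted p = 0.622), with GNLY 16.1-fold higher. B cell markers had 2 higher and 1 lower of 12 (adjusted p = 0.815), with CD22 (3.60 ± 0.58) higher. Their median (−0.02) and their mean (0.43) differed in sign. Megakaryocyte and platelet markers (3 higher of 12, adjusted p = 0.345), epithelial markers (2 lower of 14, adjusted p = 0.463) and erythroid markers (1 lower of 8, adjusted p = 0.659) did not pass. On the PMA replicate 3 array GNLY was at 8.25, against 10.56 and 11.52 on the other PMA arrays, and CD22 was at 9.93, against 8.57 and 7.44.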

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

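Outside the genes compared in the report, probe sets that the annotation used here does not name also differed between the groups. In limma over every probe set, 1546 of the 12083 unnamed probe sets passed an adjusted p of 0.05, of which 74 were at least 2-fold higher with PMA than in the unstimulated control arrays and 234 at least 2-fold lower. Of the 1754 probe sets carrying several gene symbols, 419 passed, 28 at least 2-fold higher and 101 at least 2-fold lower. The largest rises were 5.71 and 5.40 on the log2 scale. They were singled out because signal above the control arrays appeared in data the comparison did not use; no explanation was tested.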

How the results depend on the processing

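The alternative that left out both unstimulated replicate 1 and PMA replicate 3 was chosen after the data were seen; the others were set before. Main values were 4854 genes (2431 higher, 2423 lower), of which 1542 changed at least 2-fold (952 higher, 590 lower), and there were 21 lists (14 up, 7 down). Stricter criteria gave fewer by construction: 2824 genes (1509 higher, 1315 lower) at an adjusted p of 0.01, 1125 (682 higher, 443 lower) by treat against 1.5-fold, and 469 (325 higher, 144 lower) at 4-fold. A gene-wise test without shared variance gave 2843 genes (1385 higher, 1458 lower); the cause was not tested. Over every probe set, which adds sets, 2658 were higher and 3854 lower (40.8% higher, against 50.1%), and 1051 were at least 2-fold higher and 955 at least 2-fold lower (52.4% higher, against 61.7%). Without each array in turn, genes past the threshold numbered 3323 to 5042, those lower in PMA 1597 to 2449 (fewest without PMA replicate 1), those changed at least 2-fold 1430 to 1686, and lists 19 to 26. With both arrays left out there were 6310 genes, 4575 of them among the 4854, with 1717 changed 2-fold and 21 lists. With arrays centred on their medians, 2911 genes were higher and 1802 lower, and the median over all genes moved from −0.028 to 0.057.

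With an estimated correlation (−0.031 to 0.737 per list, against the preset 0.01) camera called 0 lists, 0 up and 0 down, with 6 at an unadjusted p of 0.05, while fry called 24 and camera on ranks 18. Fry called 16 of the 21 and 8 others. Ranks lost Fc and complement receptors (0.087), immediate-early and AP-1 genes (0.073) and neutrophil markers (0.0878). With genes below the median level left out, osteoclast markers (0.0566), MHC class I presentation (0.127) and pattern recognition receptors (0.309) lost their call and alternatively activated macrophage genes gained one (0.0446). With the lowest 25% left out, neutrophil markers (0.0522), Fc and complement receptors (0.0897) and pattern recognition receptors (0.163) lost theirs, and dendritic cell markers (0.0446) and eicosanoid genes (0.0458) gained one. Array quality weights lost Fc and complement receptors (0.0792), immediate-early and AP-1 genes (0.0504) and pattern recognition receptors (0.106). The mean of a gene's probe sets lost Fc and complement receptors and pattern recognition receptors (0.0503 each). The stricter adjusted p of 0.01 ended the calls of pattern recognition receptors, Fc and complement receptors, MHC class I presentation, immediate-early and AP-1 genes and neutrophil markers. With both arrays left out, Fc and complement receptors (0.066) and immediate-early and AP-1 genes (0.0878) lost theirs, and interferon-stimulated genes (0.0137) and the protein kinase C list (0.0472) gained one. Among the 10 splits of the 6 arrays into 3 and 3, 1 split, the real one, gave as many genes (4854, highest other 0, with up to 1098 at an unadjusted p of 0.05), as many genes changed 2-fold (1542, highest other 0) and as many lists (21, highest other 19). The splits are too few for a share under 0.05. Every split that mixed the groups called lists, from 9 to 19, so some gave nearly as many as the real one. Each mixed split set unequal numbers of PMA arrays against each other. Part of the PMA difference therefore stayed in its comparison, and the rest widened the spread within each side. Its list calls can come from PMA and its lack of gene calls from that spread, so these splits decide nothing about chance.

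Deviations of same-numbered arrays correlated at 0.15, −0.04 and 0.09. Unstimulated replicates 1 and 3 matched their own number best, and 2 matched PMA replicate 3 (0.11). With 3 arrays per group this cannot decide pairing, so none was assumed. With a replicate block there were 4726 genes, 1571 changed 2-fold and 21 lists. No list or named gene that was called reversed under any alternative. A change of sign was counted as a reversal only where the gene or list was called before or after it. Of 178 genes past the threshold that the naming rule picks, 155 kept their call without each array in turn. The other 23 are not among the examples in the report: RPL11, CD79A, ODC1, KRT18, PDGFRB, GAA, FOLR2, FBLN1, TNFAIP6, PLA2G4A, HLA-DMA, DDIT4, COX6C, CDKN1B, C3, TREML1, RPL22, FPR2, FDPS, FBL, PRPS1, PPP1R15A and CCL3. That choice was made after the results were seen. Of the 21 lists, 16 kept their call. The 5 that did not and the 7 others that passed without some array are given in the report. Small counts moved too: 0 lysosomal genes were lower without any 1 of the unstimulated arrays (2 with all). The table used here holds no detection calls, so genes near background cannot be told from absent ones; leaving out the lowest 25% of genes gave 4667 calls and leaving out those below the median 3635.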

Other observations

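The families, the patterns and the tests in this part were chosen after the results were seen, except the test of one chromosome region for the taste receptors, whose outcome had not been seen. Genes named below lie outside the naming rule unless the report names them, and were picked by their values. Genes were grouped by the letters their symbols start with, which made 248 families of at least 10 genes, and camera with the preset correlation called 6 at an adjusted p of 0.05; none passed with an estimated correlation (adjusted p = 0.977 for each). Metallothioneins, small metal-binding proteins, fell: 8 of 15 genes were lower and none higher, with a median log2 fold change of −0.63 (adjusted p = 0.0013), and MT1E (−2.59 ± 0.31, SE, n = 3 per group) and MT1F (−2.48 ± 0.35) changed most. These genes are near-identical copies, so their probe sets can share signal. The number lower was 4 to 10 without each array in turn (4 without PMA replicate 1, 10 without PMA replicate 2), and the median stayed below 0 under every rescaling. Of 494 zinc finger genes with ZNF symbols, most of them encoding DNA-binding proteins, 127 were lower and 18 higher, with a median of −0.17 (adjusted p = 0.000762) that was −0.09 with arrays centred on their medians, −0.10 by cyclic loess and −0.13 with quantile normalization repeated. Without PMA replicate 1, 2 or unstimulated replicate 3, 77, 85 and 81 were lower. Matrix metalloproteinases (10 higher and 1 lower of 22) and genes with ITGB symbols (7 of 11 higher, among them ITGB1BP1, an integrin-binding protein and not an integrin) rose. RPL genes fell (11 lower and 1 higher of 55), a call lost under all 3 rescalings (adjusted p 0.0652 to 0.113) and without PMA replicate 1 (0.0692, 2 lower), PMA replicate 2 (0.13, 4 lower), unstimulated replicate 1 (0.0621) or unstimulated replicate 3 (0.0581, 4 lower), with 4 lower also without unstimulated replicate 2. The ITGB call ended with cyclic loess (0.057) and without unstimulated replicate 1 (0.0596).

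Taste receptor genes were lower with PMA: of 27 measured, 15 fell and none rose, with a median of −0.43 at a low median level of 4.75 (adjusted p = 0.0013), and the largest fall was that of TAS2R60 (−1.09 ± 0.17, SE, n = 3 per group). Under the 3 rescalings 12 or 13 fell, and 8 to 14 fell without each array in turn, 8 without unstimulated replicate 3 and 9 without PMA replicate 1. In the normalized values, 10000 random lists matched on level had a median of −0.027 (central 95% −0.093 to 0.041), so genes of that level did not fall as a class. Normalization holds such lists near 0 and the family was picked for its fall. These lists therefore cannot decide whether dim signal fell before normalization. Genomic DNA in the unstimulated RNA stays open too. The 187 olfactory receptor genes within the quartiles of the taste receptors' levels had a median of −0.056 (95% bootstrap interval −0.074 to −0.038). They were dimmer (4.27), and a like fall might not show there. The 14 members on the chromosome that holds most of them fell more than the other 13, with a difference of means of −0.265 (one-sided permutation p = 0.0172). That p treats these similar genes as independent and measures the spread among genes, not arrays. RNA from that region may account for part of the fall, but this difference cannot tell it from shared hybridisation. In addition, 4 of the others fell. PRH2, a gene among the cluster, did not (0.06, adjusted p = 0.776 in limma), at a level (3.29) where a fall might not show. Shared hybridisation among these similar genes was not tested, and no biological explanation was tested beyond the PMA contrast itself.

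The PMA replicate 3 array stood apart: 367 genes lay over 2-fold from the mean of the other PMA arrays, against 41 and 181 for PMA replicates 1 and 2, and it was singled out by its place on the second principal component (28.5). TNFSF18 (7.55 against 3.45 and 3.81), PLK2 (10.81 against 7.91 and 6.72) and MRC1 were higher there and STC1 (7.68 against 10.30 and 10.68), GNLY and CCL20 lower, picked from among the genes that deviated most. Undifferentiated cells mixed in are argued against at the share required. Of the 147 genes at least 8-fold higher with PMA, chosen without this array, 120 were lower on it, which would need 40.6% of such cells. That share would need a median rise of 2.46 in the 56 genes at least 8-fold lower, also chosen without this array. The rise there was 0.088 (95% bootstrap interval over these genes −0.104 to 0.266). Both sets were chosen by their values on PMA replicates 1 and 2, with which this array was then compared. Part of either deviation is therefore built in, so the 40.6% may be too high, and a smaller share is not excluded. Compressed signal on the array stays open, because random genes of the same level (median deviation 0.007, central 95% −0.036 to 0.05, against −0.68 for the 147 genes) are held near 0 by normalization and decide nothing. No biological explanation was tested, since the labels describe the PMA arrays alike.

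The unstimulated replicate 1 array stood apart in another set: 158 genes lay over 2-fold from the other unstimulated arrays, against 16 and 25 for the others, fewer than the 181 of PMA replicate 2, and its second principal component was −32.8. Of the cholesterol synthesis genes, 17 of 18 were lower there, with a median deviation of −1.09. HMGCS1 was 8.82 there and 10.93 and 11.08 on the others, JUN 6.58 against 9.03 and 9.11 and SPP1 9.86 against 12.17 and 12.15, picked from among the genes that deviated most, though TNF (in the report) deviated more. Examples in the report that were also lower there include RGS1 (4.38 against 6.08 and 6.15) and LY96 (4.67 against 6.21 and 6.30). Relative to each gene's mean, the median cholesterol synthesis gene lay at −0.21 there. The PMA arrays lay at −0.39, −0.34 and −0.67 and the other unstimulated arrays at 0.73 and 0.76. PMA-treated cells mixed in would therefore have to be a large share to lower these genes so far. Such a share would raise the genes higher with PMA, and is argued against. The 117 genes at least 8-fold higher with PMA, chosen without this array, had a median deviation of −0.146 (95% bootstrap interval −0.257 to −0.074), not above 0. That interval measures the spread among genes on 1 array, and 83 of the 117 were lower there. A small share of such cells, hidden by another fall of these genes, is not excluded, but would not account for the lower cholesterol synthesis genes. Compressed signal on the array stays open, because random lists of the same level (median 0.05, central 95% −0.11 to 0.21) are held near 0 by normalization and the cholesterol list was picked for its deviation, and no biological explanation was tested, since the labels describe the unstimulated arrays alike.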
